A study of Mus musculus with 8 samples.

How the data were processed

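Total RNA-seq libraries of a mouse pancreatic ductal adenocarcinoma cell line were analysed in 4 groups of 2: control, Paf1 knockdown, Myc knockdown and both knockdowns. Doxycycline at 1 µg/mL was given in the Paf1 knockdown groups, per the labels' protocols, so the design does not separate doxycycline from Paf1 knockdown. Groups and library numbers came from the sample titles. One Myc knockdown title carries no number, and the column numbered 1 was taken as that library because the other title carries number 2.

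The authors deposited raw read counts per region, in 1 table of 590 eRNA regions and 1 of 437 PROMPT regions. Trim Galore 0.6.4, STAR 2.7.1a and featureCounts 1.6.4 were used on mm10 (GRCm38.p6), per the submitters' processing notes, which give neither order nor options. How the regions were defined, whether counting used strand and how reads with several matches were treated are not given in the sources used here. The tables hold part of each library, so their totals (17190 to 29612 counts) are not the sequencing depth, which is not given in the sources used here.

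Regions were placed on GENCODE M21 gene models of the same build. A PROMPT was given the gene whose start site lay within 5 kb, and an eRNA the nearest protein-coding start site within 100 kb, a link by distance only. Of the PROMPTs, 435 had such a gene and all 435 lay on the strand opposite to it; 484 eRNAs had one. No region overlapped an annotated exon on its own strand, but 238 eRNAs and 175 PROMPTs overlapped a gene body. Within 10 kb downstream of a gene on the same strand lay 31 PROMPTs, the Gapdh PROMPT among the named ones, where readthrough of that gene could supply reads. If counting did not use strand, reads of those genes cannot be told apart from the eRNA or PROMPT, so values of regions over a gene, such as the PROMPTs of Egr1, Pomp, Pcif1 and Aqp5, are uncertain in that respect.

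Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Regions were kept with filterByExpr (minimum count 10, minimum total 15) over both tables, which left 496 of 1027 regions (267 eRNAs and 229 PROMPTs). TMM factors were computed over both tables together. Each table was fitted on its own with 4 group means over all 8 libraries (4 residual degrees of freedom), glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment within the table and a threshold of 0.05. Standard errors are the log2 change divided by the square root of F. Normalised counts are counts divided by the effective library size and multiplied by its mean. Class medians and gene lists were tested with limma's fry (two-sided, directional), with Benjamini-Hochberg adjustment over the 10 medians or over the lists of a contrast, and lists also with camera. The 5 contrasts were Paf1 knockdown in shControl and in shMyc cells, Myc knockdown without and with Paf1 knockdown, and the interaction.

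The groups, tests, gene lists, the rule for named regions and the alternatives were fixed before the data were examined, except where said otherwise. Named regions had an adjusted p below 0.05, both libraries of a group outside the range of the other group (not asked of the interaction) and a mean at or above the median region of the table. Of these the 6 largest rises and 6 largest falls per contrast and class were taken. Regions at Paf1 or Myc and members past the threshold of lists with a fry adjusted p below 0.05 were added; the Ier3 and Phlda1 eRNAs named in other contrasts were chosen after their values were seen.

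The test was checked on simulated counts for Paf1 knockdown in shControl cells, with 200 regions changed and 465 tested. It recovered 46.5% of 43 regions changed 2-fold and 92.7% of 55 changed 4-fold, and called 3 of 367 unchanged regions. All regions of a class were given a common spread, and as many were raised as lowered. These rates therefore do not cover a shift of one class against the other or a spread that varies between regions. The libraries of a group differed by more than sampling noise (chi-square over degrees of freedom 1.11 in control, chi-square p = 0.0390, and 1.33 to 1.44 in the other groups), so none was treated as a copy.

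The alternatives were no filter and a stricter filter on low counts, DESeq2 1.42.0 size factors, library totals as scale, the DESeq2 Wald test, fits of the 4 libraries compared, the replicate number as a block, each library left out, and eRNAs over any gene body and PROMPTs over a gene other than their own left out. TMM inside each table, a crossed replicate block, the split of the control libraries (log2 of normalised counts plus 1) and the adjusted fry values of the medians under each scaling over both tables were added after seeing the data. TMM inside each table centres each class on itself, so it was used for single regions and gene lists and not for class medians. Centring also draws the split of higher and lower regions toward balance, so that split does not bear on the direction of a class. Where a library was left out, its partner was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.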

Results

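Total RNA was sequenced from mouse pancreatic ductal adenocarcinoma (PDAC) cells, a cultured tumour line, in a design that crossed knockdown of Paf1 with knockdown of Myc. Paf1 is a core subunit of the PAF1 complex, which travels with RNA polymerase II, and Myc is a transcription factor that drives growth genes. Paf1 was repressed with doxycycline-induced dCas9-KRAB, a catalytically dead Cas9 fused to a silencing domain. Myc knockdown refers to shMyc cells, and shControl cells served as their control. Each Myc comparison sets shMyc against shControl cells, so other differences between these cells cannot be told apart from Myc knockdown. There were 4 groups of 2 libraries: control (shControl), Paf1 knockdown (shControl with Paf1 knockdown), Myc knockdown (shMyc) and double knockdown (shMyc with Paf1 knockdown). The deposited tables held read counts for 590 enhancer RNA (eRNA) regions, noncoding transcripts made at enhancers, and 437 promoter upstream transcript (PROMPT) regions, transcribed away from gene promoters on the opposite strand. Over both tables a library held 17190 to 29612 counts, which limits the power to call small changes of single regions. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

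The knockdowns themselves could not be read from these tables. No eRNA or PROMPT region lay at Paf1. The single region linked to Myc (chromosome 15, 62038400 to 62039600, minus strand, 50978 bp from the Myc start site) held 0 counts in each control and Myc knockdown library. It held 3 and 2 counts in the Paf1 knockdown libraries and 2 and 5 in the double knockdown libraries, too few to test.

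The balance between both classes of transcript separated control from every knockdown group. eRNA regions took 61.9% ± 0.30 of the counts in control (SD, n = 2), 51.8% ± 0.046 after Paf1 knockdown, 49.1% ± 0.32 after Myc knockdown and 49.2% ± 0.087 after the double knockdown. In control library 1 the share was 61.6%, with an exact 95% binomial interval of 61.0% to 62.3%; such intervals cover counting error only. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, and no model of the shares was fitted. The depth of the whole libraries is not given in the sources used here. A lower eRNA share therefore cannot be separated from a higher PROMPT level, and all changes below are relative to a reference scale (TMM) over both tables.

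**Figure D1:**
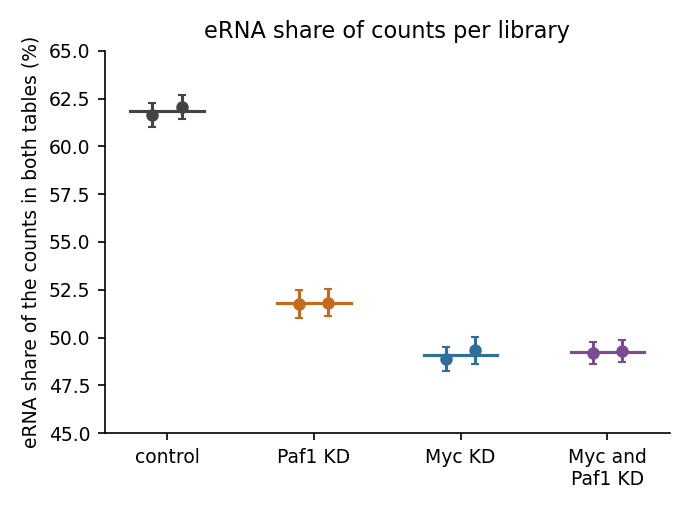
Percentage of the counts in both tables that fell in eRNA regions, for the 2 libraries of each group (points, with exact 95% binomial intervals) and the group mean (line); the vertical axis starts at 45%. The control libraries lie at 61.6% and 62.1%, and the other 6 libraries lie between 48.9% and 51.8%.

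The first comparison asked which eRNAs responded to Paf1 knockdown in shControl cells. An eRNA 21554 bp from Ier5, an immediate-early response gene (chromosome 1, 155076207 to 155078082), fell from 39.1 ± 4.2 to 4.10 ± 3.9 normalised counts (SD, n = 2 per group; log2 change -3.16, SE 0.47, edgeR adjusted p = 1.12e-05). An eRNA near Tns3, which encodes a focal adhesion protein (chromosome 11, 8675400 to 8680000), fell from 155 ± 4.8 to 26.3 ± 1.5. An eRNA 74439 bp from Cebpb, a C/EBP transcription factor gene, fell from 39.7 ± 6.8 to 5.56 ± 1.4, and an intergenic eRNA on chromosome 5 (64579137 to 64580534) fell from 104 ± 11 to 19.2 ± 6.0. In the other direction, an eRNA 10172 bp from the calsyntenin gene Clstn3 rose from 2.95 ± 0.77 to 18.7 ± 4.4 normalised counts (log2 change 2.62, SE 0.55, edgeR adjusted p = 0.000808).

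In all, 53 of 267 eRNA regions were lower and 18 were higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Rises were also called near Nfyc (log2 change 2.62), Kansl1 (2.56), Cyb5b (1.81), Cldn5 (1.76) and Rbpj (1.51), from 1.77 to 7.67 normalised counts in control. The regions at Nfyc and Rbpj cover a start site of the gene, and that at Kansl1 lies 509 bp from one. All lie on the strand opposite to the gene, so position does not separate them from PROMPTs. Falls were also called at intergenic eRNAs on chromosome 7 at 145045672 (-2.73) and chromosome 8 at 10665462 (-2.65). The split was 32 higher and 34 lower with library totals as scale and 25 higher and 35 lower with TMM inside each table, and 34 lower and 18 higher eRNAs were called under all 4 scalings. Here and below, TMM inside each table centres the class, so its split does not bear on the direction of the class. The 71 calls numbered 37 without control library 2 and 40 without Paf1 knockdown library 2. The chromosome 8 eRNA was called under 2 of the 4 scalings. The call at Nfyc was lost without control libraries 1 or 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.115) and that at Kansl1 was lost without control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.426). The call at Cyb5b was lost without control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.116) and that at Cldn5 was lost without control library 1 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.0862). The call at Rbpj was lost without control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.20) and that at chromosome 8 was lost without control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.238). With 1 library left out, the log2 change ran from 1.31 to 3.28 at Kansl1, from -4.78 to -2.48 at Ier5, from -4.13 to -2.09 at chromosome 7 and from -6.10 to -1.80 at chromosome 8. Calls were lost with the DESeq2 Wald test at Nfyc, Kansl1, Cyb5b, Rbpj and chromosome 8, with no filter on low counts at Cyb5b, Rbpj and chromosome 8 and without eRNAs over gene bodies at chromosome 8. They were also lost with a replicate block at Rbpj and chromosome 8.

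PROMPTs moved mostly the other way in the same comparison, with 34 of 229 higher and 14 lower. The PROMPT of Aqp5, a water channel gene (chromosome 15, 99583600 to 99590800, antisense to Aqp5 and Aqp2), fell from 787 ± 25 to 233 ± 11 normalised counts (SD, n = 2 per group; log2 change -1.76, SE 0.11, edgeR adjusted p = 6.45e-25). PROMPTs of Tmco4 (log2 change -1.78), the ETS factor gene Elf4 (-1.68), the Cdc42 effector gene Cdc42ep2 (-1.42), the ubiquitin ligase gene Hectd1 (-1.23) and Rwdd2b (-1.44) also fell. The PROMPT of Egr1, an immediate-early transcription factor gene (chromosome 18, 34858000 to 34860600, antisense to Egr1), rose from 6.56 ± 4.3 to 28.4 ± 7.7 normalised counts (log2 change 2.09, SE 0.47, edgeR adjusted p = 0.000390). PROMPTs of the glycolytic gene Gapdh (over Ncapd2 and downstream of Iffo1 on the same strand, 13.0 to 41.8), the ribosomal protein gene Rps5 (10.1 to 31.1), the proteasome assembly gene Pomp (6.0 to 21.8), Wdr1 (8.84 to 30.3) and Angel2 (8.87 to 26.9) rose too.

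The PROMPT split was 75 higher and 9 lower with library totals and 16 higher and 18 lower with TMM inside each table, and 16 higher and 9 lower PROMPTs were called under all 4 scalings. The 48 calls numbered 30 without control library 1 and 24 without control library 2. Rwdd2b was called under 2 of the 4 scalings. The call at the Egr1 PROMPT was lost without control library 2 (edgeR adjusted p = 0.0714) and that at Pomp was lost without control library 2 (edgeR adjusted p = 0.211). The call at Wdr1 was lost without control library 1 (edgeR adjusted p = 0.102) and that at Rps5 was lost without control library 2 (edgeR adjusted p = 0.0728). The call at Rwdd2b was lost without Paf1 knockdown library 1 or control library 2 (edgeR adjusted p up to 0.566). The log2 change ran, with 1 library left out, from 1.02 to 4.10 at Pomp and from -2.76 to -0.68 at Rwdd2b. Under other settings, calls were lost with the DESeq2 Wald test at Rwdd2b, with no filter on low counts at Rwdd2b and with the stricter filter at Rwdd2b. They were also lost without PROMPTs over another gene at Rwdd2b and with a replicate block at Rwdd2b.

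Paf1 knockdown was then compared in shMyc cells. Of 267 eRNAs, 2 passed, both lower here and in shControl cells. An eRNA 63925 bp from the cadherin gene Cdh6 (chromosome 15, 13237600 to 13245600) went from 122 ± 13 to 62.2 ± 18 normalised counts (SD, n = 2 per group; log2 change -0.97, SE 0.21, edgeR adjusted p = 0.0245). An eRNA 39188 bp from Plekhg6 (chromosome 6, 125419981 to 125425789) went from 355 ± 9.9 to 224 ± 22 (log2 change -0.67, SE 0.15, edgeR adjusted p = 0.0245). At an unadjusted p below 0.05 there were 51 eRNAs, and the DESeq2 Wald test called 2. Neither call was made with DESeq2 size factors or with TMM inside each table, and the split was 1 higher and 2 lower with library totals. The count was 0 without control library 1, control library 2 or double knockdown library 2, 1 without Myc knockdown library 1, 5 without Myc knockdown library 2 and 9 without double knockdown library 1. The call at Cdh6 was lost without Myc knockdown library 2, double knockdown library 2 or control libraries 1 or 2 (edgeR adjusted p up to 0.166) and that at Plekhg6 was lost without Myc knockdown library 1, double knockdown library 2 or control libraries 1 or 2 (edgeR adjusted p up to 0.144). Calls were lost with no filter on low counts at Plekhg6, with only the 4 libraries compared at Cdh6 and Plekhg6 and without eRNAs over gene bodies at Cdh6 and Plekhg6. They were also lost with a replicate block at Cdh6 and Plekhg6.

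In shMyc cells 25 of 229 PROMPTs were higher and 11 lower after Paf1 knockdown. The Egr1 PROMPT rose from 5.08 ± 0.85 to 21.6 ± 9.4 normalised counts (SD, n = 2 per group; log2 change 2.05, SE 0.47, edgeR adjusted p = 0.00163). The PROMPTs of Pomp (17.7 to 42.9) and Angel2 (13.0 to 29.8) also rose, as did those of Ccdc43 (log2 change 1.65), the general transcription factor gene Gtf2a1 (1.43) and Spg7 (1.31). The PROMPT of Smad3, a TGF-beta signal transducer (chromosome 9, 63758526 to 63760326), fell from 88.6 ± 11 to 43.3 ± 0.91 (log2 change -1.04, SE 0.20, edgeR adjusted p = 0.000537). PROMPTs of the thioredoxin gene Txn1 (log2 change -1.24), the ductal keratin gene Krt19 (-0.94), Cdc42ep2 (-0.91), the clock gene Per2 (-0.87) and the Notch target gene Hes1 (-0.83) fell as well.

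Of these PROMPTs, Smad3 kept its call with each library left out in turn. The 36 calls numbered 12 and 20 without Myc knockdown libraries 1 and 2, 11 without double knockdown library 2, and 20 and 22 without control libraries 1 and 2. The call at the Egr1 PROMPT was lost without double knockdown library 2 (edgeR adjusted p = 0.10) and that at Pomp was lost without Myc knockdown library 1 (edgeR adjusted p = 0.0817). The call at Angel2 was lost without Myc knockdown library 1 (edgeR adjusted p = 0.118) and that at Ccdc43 was lost without Myc knockdown library 1 or double knockdown library 2 (edgeR adjusted p up to 0.185). The call at Gtf2a1 was lost without Myc knockdown libraries 1 or 2, double knockdown libraries 1 or 2 or control libraries 1 or 2 (edgeR adjusted p up to 0.147) and that at Spg7 was lost without Myc knockdown libraries 1 or 2, double knockdown library 1 or control libraries 1 or 2 (edgeR adjusted p up to 0.339). The call at Txn1 was lost without Myc knockdown library 1, double knockdown libraries 1 or 2, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.501) and that at Krt19 was lost without Myc knockdown libraries 1 or 2, double knockdown libraries 1 or 2 or control library 1 (edgeR adjusted p up to 0.177). The call at Cdc42ep2 was lost without Myc knockdown libraries 1 or 2 or double knockdown library 2 (edgeR adjusted p up to 0.258) and that at Per2 was lost without Myc knockdown libraries 1 or 2, double knockdown library 2 or control libraries 1 or 2 (edgeR adjusted p up to 0.360). The call at Hes1 was lost without Myc knockdown library 2 or double knockdown library 2 (edgeR adjusted p up to 0.192). Leaving out 1 library gave log2 changes from 1.07 to 2.45 at Ccdc43, from 0.82 to 1.67 at Spg7, from -1.57 to -0.75 at Txn1 and from -1.27 to -0.55 at Per2. Under other settings, calls were lost with the DESeq2 Wald test at Krt19, Cdc42ep2 and Hes1, with no filter on low counts at Txn1, Krt19, Cdc42ep2 and Per2 and with only the 4 libraries compared at Gtf2a1, Spg7, Txn1, Krt19 and Per2. They were also lost without PROMPTs over another gene at Txn1 and Per2 and with a replicate block at Gtf2a1, Spg7, Txn1 and Per2. DESeq2 gave no adjusted value at Egr1, Ccdc43, Gtf2a1, Spg7, Pomp, Angel2, Txn1 and Per2, set aside by its own filter.

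Across regions, the log2 change after Paf1 knockdown in shControl cells had a Pearson correlation with that in shMyc cells of 0.05 for 267 eRNAs and 0.08 for 229 PROMPTs, and of 0.27 for the 115 more abundant PROMPTs. Regions are not independent replicates, so no p-value is attached. Among PROMPTs, 8 were higher in both backgrounds, 2 were lower in both and 2 went in opposite directions.

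**Figure D2:**
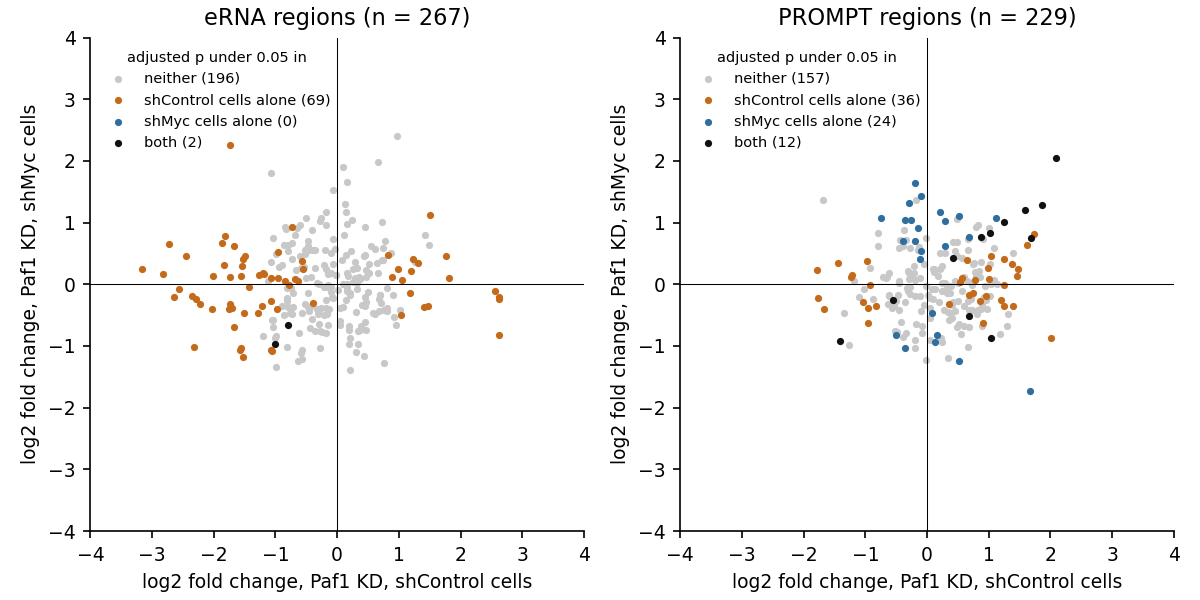
Log2 fold change after Paf1 knockdown in shControl cells (horizontal) and in shMyc cells (vertical), for 267 eRNA regions (left) and 229 PROMPT regions (right), each point a region measured in 2 libraries per group. Of the eRNAs, 69 were called in shControl cells alone and 2 in both, and of the PROMPTs 36 in shControl cells alone, 24 in shMyc cells alone and 12 in both.

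Myc knockdown was compared first in cells without Paf1 knockdown. An abundant eRNA antisense to the receptor phosphatase gene Ptprd (chromosome 4, 77310809 to 77326205) fell from 1290.3 ± 14 to 79.5 ± 9.4 normalised counts (SD, n = 2 per group; log2 change -4.01, SE 0.15, edgeR adjusted p = 1.11e-17). An eRNA antisense to the dynein heavy chain gene Dnah14 (chromosome 1, 181611472 to 181627698) fell from 581 ± 58 to 41.8 ± 4.3. eRNAs near Usp6nl, a Rab GTPase-activating protein gene (125 to 10.7), near the interferon gamma receptor gene Ifngr1 (39.1 ± 0.90 to 2.80 ± 4.0), on chromosome 5 at 64579137 (104 to 7.15) and on chromosome 7 at 145045672 (25 to 1.98) fell too. An eRNA 12341 bp from the organic anion transporter gene Slco4a1 (chromosome 2, 180438293 to 180443904) rose from 69.9 ± 0.067 to 299.7 ± 49.9 (log2 change 2.10, SE 0.18, edgeR adjusted p = 3.01e-10). Rises were also called near Kansl1, a subunit gene of a histone acetyltransferase complex (log2 change 3.60), Vmn2r13 (2.38), Abhd2 (2.30), the actin-binding gene Ablim1 (2.10) and the hyaluronan receptor gene Cd44 (2.01). The eRNAs near Kansl1 (509 bp), Ablim1 (369 bp) and Usp6nl (2188 bp) lie opposite to the gene within the 5 kb used for PROMPTs. Position does not separate them from PROMPTs.

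In this comparison 79 of 267 eRNAs were lower and 33 higher. The split was 53 higher and 63 lower with library totals and 54 higher and 62 lower with TMM inside each table, and 62 lower and 31 higher eRNAs were called under all 4 scalings. The call at the Abhd2 eRNA was lost without control library 2 (edgeR adjusted p = 0.102). The log2 change ran, with 1 library left out, from -8.31 to -2.78 at Ifngr1. DESeq2 gave no adjusted value at Abhd2 and chromosome 7, set aside by its own filter.

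Of 229 PROMPTs, 48 were higher and 24 lower after Myc knockdown. The PROMPT of Pcif1, which encodes a cap-specific RNA methyltransferase (chromosome 2, 164874775 to 164879679, antisense to Pcif1), rose from 93.0 ± 1.3 to 353 ± 19.6 normalised counts (SD, n = 2 per group; log2 change 1.93, SE 0.14, edgeR adjusted p = 2.60e-21). Rises were also called at the mitochondrial ribosome gene Mrpl45 (log2 change 2.68), Caprin1 (2.04), the kinase gene Dyrk1a (2.01), Fbxw4 (1.76) and the nucleosome-binding gene Hmgn2 (1.76). The Aqp5 PROMPT fell from 787 ± 25 to 175 ± 3.1 (log2 change -2.17, SE 0.11, edgeR adjusted p = 1.46e-30). PROMPTs of the calcium pump gene Atp2b1 (59.9 to 13.7), the chemokine gene Cxcl5 (39.0 to 9.39), the ATP synthase gene Atp5g1 (63.9 to 17.3), Tmco4 (65.2 to 18.1) and the kinase gene Rps6ka4 (33.7 to 9.77) fell. The PROMPT split was 83 higher and 15 lower with library totals and 27 higher and 37 lower with TMM inside each table, and 27 higher and 15 lower PROMPTs were called under all 4 scalings. Without control library 1 the 72 calls became 42. The call at Caprin1 was lost without Myc knockdown library 2 or control libraries 1 or 2 (edgeR adjusted p up to 0.154) and that at Hmgn2 was lost without Myc knockdown library 1 or control library 2 (edgeR adjusted p up to 0.189). With 1 library left out, the log2 change ran from 1.94 to 4.40 at Mrpl45 and from 1.20 to 2.75 at Hmgn2. Calls were lost with the DESeq2 Wald test at Caprin1 and Hmgn2.

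**Figure D3:**
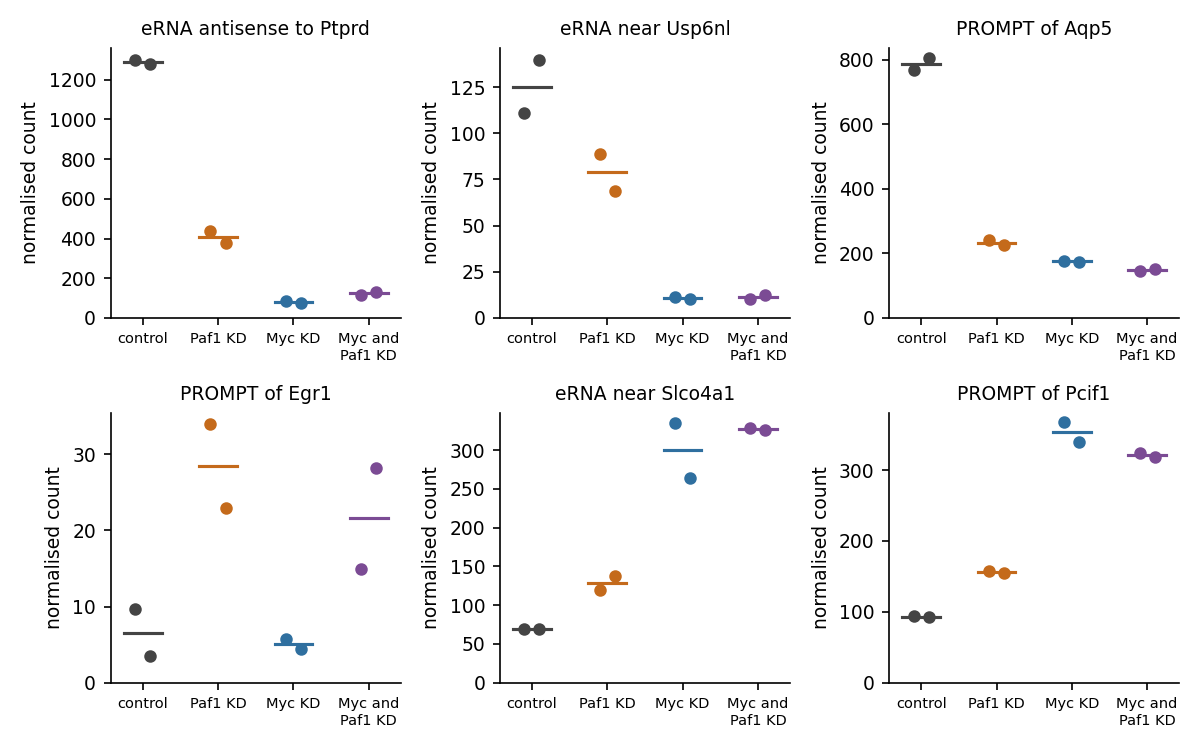
Normalised counts (TMM over both tables) of 6 named regions in the 2 libraries of each of the 4 groups, with points for libraries and lines for group means; each vertical axis is linear and starts at 0. The Ptprd antisense eRNA has means of 1290.3 in control and 79.5 in Myc knockdown, and the Slco4a1 eRNA 69.9 and 299.7, while the Egr1 PROMPT has 6.56 in control and 28.4 in Paf1 knockdown.

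Myc knockdown was also compared in cells with Paf1 knockdown. The Usp6nl eRNA (chromosome 2, 6347007 to 6350545) fell from 78.8 ± 14 to 11.4 ± 1.3 normalised counts (SD, n = 2 per group; log2 change -2.77, SE 0.29, edgeR adjusted p = 6.41e-08), and the Dnah14 eRNA from 179 ± 22 to 31.8 ± 10.2. eRNAs near Stard13, a Rho GTPase-activating protein gene (35.4 to 6.26), the tight junction gene Cldn5 (chromosome 16 at 18732000, 55.3 to 11), Mocs2 (10.1 to 1.10) and the actin-depolymerising gene Dstn (13.6 to 2.59) fell. An intergenic eRNA on chromosome 6 (84313776 to 84320159) rose from 29.8 ± 3.4 to 150 ± 16 (log2 change 2.32, SE 0.24, edgeR adjusted p = 4.99e-08). Rises were also called near the survival gene Bcl2l1 (log2 change 2.92), Abhd2 (1.95), Gm17555 (1.85) and Sorbs2 (1.61) and on chromosome 8 at 10665462 (3.60). In this comparison 35 of 267 eRNAs were lower and 28 higher, and the balance turned with no filter on low counts (31 higher and 20 lower). Without Paf1 knockdown library 2 the 63 calls became 39. The call at Abhd2 was lost without double knockdown library 1 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.111) and that at Gm17555 was lost without control library 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.363). The call at Mocs2 was lost without Paf1 knockdown library 1 (edgeR adjusted p = 0.261) and that at Dstn was lost without double knockdown library 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.0886). The crossed replicate block, chosen after the data were seen, left 10 calls. It was fitted to the 4 libraries compared alone, with fewer residual degrees of freedom than the main fit, so the drop does not isolate an effect of pairing. The log2 change ran, with 1 library left out, from 2.75 to 7.05 at chromosome 8, from 0.78 to 7.04 at Gm17555 and from -3.69 to -1.95 at Mocs2. Under other settings, calls were lost with the DESeq2 Wald test at Bcl2l1, Abhd2, Gm17555 and Dstn, with a replicate block at Gm17555 and with a crossed replicate block at chromosome 8, Bcl2l1, Abhd2, Gm17555, Sorbs2, Mocs2 and Dstn.

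Of 229 PROMPTs in the same comparison, 23 were higher and 17 lower. The PROMPT of the calcium channel subunit gene Cacnb3 (chromosome 15, 98626000 to 98633400) rose from 50.6 ± 11 to 143 ± 12 normalised counts (SD, n = 2 per group; log2 change 1.51, SE 0.20, edgeR adjusted p = 2.87e-09). Rises were also called at Dis3l, an exosome nuclease gene (log2 change 2.29), Serpinb6b (1.73), Clasp2 (1.6), the chromatin remodeller gene Bptf (1.6) and Brd1 (1.49). PROMPTs of Eppk1, an epithelial cytolinker gene (84.2 to 20.9), Krt19 (48.0 to 13.6), Atp5g1 (36.4 to 13.6), Plek2 (33.0 to 13.2), Txn1 (22.0 to 6.60) and Cdc42bpb (14.0 to 2.55) fell. The balance turned with the DESeq2 Wald test (7 higher and 10 lower) and without Paf1 knockdown library 2. With TMM inside each table the split was 18 higher and 21 lower, which does not bear on the balance because that scaling centres the class. The 40 calls numbered 22 without double knockdown library 2 and 25 without Paf1 knockdown library 2. Clasp2 was called under 3 of the 4 scalings. The call at Dis3l was lost without double knockdown library 2 (edgeR adjusted p = 0.0772) and that at Serpinb6b was lost without double knockdown library 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.317). The call at Clasp2 was lost without Myc knockdown library 2, double knockdown library 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.231) and that at Bptf was lost without double knockdown library 1 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.218). The call at Brd1 was lost without double knockdown library 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.103) and that at Plek2 was lost without Paf1 knockdown library 1 (edgeR adjusted p = 0.191). Leaving out 1 library gave log2 changes from -1.69 to -0.79 at Plek2. Calls were lost with the DESeq2 Wald test at Dis3l, Bptf and Brd1 and with a replicate block at Serpinb6b and Clasp2. DESeq2 gave no adjusted value at Serpinb6b and Clasp2, set aside by its own filter.

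The Myc responses without and with Paf1 knockdown are contrasts of different libraries. Their log2 changes had a Pearson correlation across regions of 0.51 for eRNAs and 0.37 for PROMPTs. Any other difference between shMyc and shControl cells would enter both contrasts. Among eRNAs 25 were lower in both, 14 higher in both and 1 opposite, and among PROMPTs 6 were lower in both and 12 higher in both.

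The Paf1 response in shControl cells and the Myc response without Paf1 knockdown were measured against the same 2 control libraries. Of the eRNAs, 40 were lower in both and 8 higher in both, where independent lists would share 15.7 and 2.22. Their log2 changes had a Pearson correlation of 0.65 and a covariance of 0.801, against 0.49 and 0.107 in 50 simulations of unchanged groups. The simulations used a common spread for all regions of a class. Of the PROMPTs, 12 were lower in both, 14 higher in both and 1 opposite, where independent lists would share 1.47 and 7.13. The PROMPT correlation was 0.65 (simulated 0.53) and the covariance 0.446 (simulated 0.123). With 1 control library for each contrast, both ways round, the eRNA covariance of log2 normalised counts was 0.669 and 0.648, against 0.776 and 0.842 with the same library for both. For PROMPTs it was 0.321 and 0.327, against 0.529 and 0.532. This split was chosen after the data were seen, and it leaves any difference that both control libraries share.

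The interaction asked whether the Paf1 response differed with Myc knocked down. The Ifngr1 eRNA went from 39.1 ± 0.90 to 11.8 ± 5.4 normalised counts in shControl cells and from 2.80 ± 4.0 to 12.8 ± 4.4 in shMyc cells (SD, n = 2 per group), an interaction of 4.0 on the log2 scale (SE 0.79, edgeR adjusted p = 0.000745). With 1 library left out it ran from 2.92 to 8.46. Interactions were also positive at eRNAs near Ier5 (3.41), Cebpb (2.98) and Ly6e (2.88) and on chromosome 5 at 64579137 (2.91), and negative near Clstn3 (-2.82). The Ier5, Cebpb and chromosome 5 eRNAs were already low in Myc knockdown, at 4.61, 7.49 and 7.15 normalised counts. In control they held 39.1, 39.7 and 104, so little room was left for a further fall in shMyc cells. Among PROMPTs the interaction was 1.54 at Aqp5 (SE 0.17, edgeR adjusted p = 7.82e-12) and 2.01 at Tmco4, both of which started lower in Myc knockdown (175 and 18.1 normalised counts) than in control. The PROMPT of the transcriptional repressor gene Irf2bp2 went from 88.8 ± 3.0 to 143 ± 10.3 in shControl cells and from 178 ± 3.4 to 126 ± 6.8 in shMyc cells, an interaction of -1.19 (SE 0.23, edgeR adjusted p = 0.000123).

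The interaction was positive at 31 and negative at 8 of 267 eRNAs, and positive at 14 and negative at 16 of 229 PROMPTs. Of the 53 eRNAs lower after Paf1 knockdown in shControl cells, 28 had a positive interaction past the threshold. The same fall enters the interaction with the opposite sign, so the way these regions were chosen favours a positive interaction. The eRNA split was 21 higher and 21 lower with library totals and 22 higher and 12 lower with TMM inside each table. The split was 20 positive and 0 negative with the DESeq2 Wald test, 36 positive and 2 negative with no filter on low counts and 27 positive and 1 negative with a replicate block. The PROMPT split was 5 higher and 51 lower with library totals, 19 higher and 6 lower with TMM inside each table and 12 higher and 8 lower with DESeq2 size factors. It was 18 positive and 8 negative with no filter on low counts, 3 positive and 2 negative without control library 1, 12 positive and 10 negative without double knockdown library 2 and 11 positive and 10 negative without Paf1 knockdown library 2. The eRNA calls numbered 21 without control library 2, and the PROMPT calls 5 without control library 1 and 19 without Myc knockdown library 1.

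Over all tested regions of a class, the median log2 change went with the shares. After Paf1 knockdown in shControl cells it was -0.22 for eRNAs (limma fry adjusted p = 0.000447, over 10 medians) and 0.25 for PROMPTs (adjusted p = 0.00467). After Myc knockdown without Paf1 knockdown it was -0.21 for eRNAs (limma fry adjusted p = 0.000395) and 0.27 for PROMPTs (adjusted p = 0.00385). In shMyc cells Paf1 knockdown gave -0.02 for eRNAs (limma fry adjusted p = 0.431) and -0.02 for PROMPTs (adjusted p = 0.431). Myc knockdown with Paf1 knockdown gave -0.08 for eRNAs (limma fry adjusted p = 0.00899) and 0.04 for PROMPTs (adjusted p = 0.224). The interaction medians were 0.14 (limma fry adjusted p = 0.00167) and -0.27 (adjusted p = 0.00888).

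These medians describe eRNAs relative to PROMPTs, since scaling removes a shift shared by both classes. Library totals as scale moved control against the other groups by -0.35 on the log2 scale, and TMM inside each table by -0.31 for eRNAs and 0.23 for PROMPTs. With library totals the eRNA medians turned to 0.15 for Paf1 in shControl cells, 0.13 for Myc without Paf1 knockdown and -0.20 for the interaction. After adjustment over the 10 medians none of these 3 tests then passed (fry adjusted p = 0.359, 0.119 and 0.249). For Myc without Paf1 knockdown its direction stayed lower, because fry follows the average of standardised effects. TMM inside each table centres each class on itself, so the medians were not tested under it. The PROMPT medians of the same 3 contrasts kept their sign and the direction of their fry tests under the 3 scalings over both tables. With DESeq2 size factors the PROMPT interaction no longer passed after that adjustment (fry adjusted p = 0.0692). For Myc with Paf1 knockdown, the eRNA median no longer passed without double knockdown library 2 (-0.09), and the PROMPT median passed without Paf1 knockdown library 1 (0.10). For Paf1 in shMyc cells, the eRNA median was 0.05 and the PROMPT median 0.03 without Myc knockdown library 2. The eRNA median there passed without double knockdown library 1 (-0.0508) or control library 2 (-0.0451). The tests with a library left out used the unadjusted fry value of each median.

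Of 19 gene lists, the Kras-MAPK response list alone reached 5 tested regions, 9 eRNAs near Ier5, Lif, Fos, Hbegf, Phlda1 and Ier3. As the only list tested, its adjusted fry and camera values equal the unadjusted ones, and no adjustment was made over the 5 contrasts. After Paf1 knockdown in shControl cells 1 of the 9 passed, the Ier5 eRNA at 155076207, which fell, and adjusted over the list alone the count was 1. The list moved lower on balance (limma fry adjusted p = 0.00638), with an adjusted p = 0.782 with an estimated correlation in camera. That call ended with library totals (limma fry adjusted p = 0.241) and with TMM inside each table (adjusted p = 0.0673). After Myc knockdown without Paf1 knockdown, the Ier3 eRNA rose (log2 change 1.94) and those near Ier5 (-3.05) and Phlda1 (-1.82) fell (limma fry adjusted p = 0.317); adjusted over the list alone the count was 1 higher and 2 lower. The Phlda1 call was lost with library totals (edgeR adjusted p = 0.0751), with TMM inside each table (adjusted p = 0.0805) and with a replicate block (adjusted p = 0.0576). With Paf1 knockdown the Ier3 eRNA rose (1.43; 1 adjusted over the list alone), and the list moved higher (limma fry adjusted p = 0.0264; adjusted p = 0.254 with an estimated correlation). In shMyc cells the smallest p after Paf1 knockdown was at the Ier3 eRNA (log2 change -0.77, edgeR adjusted p = 0.122; 0.0905 adjusted over the list alone), with a list value of limma fry adjusted p = 0.680. The interaction passed at the Ier5 eRNA (1 adjusted over the list alone), with limma fry adjusted p = 0.0433 for the list and adjusted p = 0.839 with an estimated correlation. It ended with library totals (limma fry adjusted p = 0.558), with TMM inside each table (adjusted p = 0.218) and with the replicate number as a block (adjusted p = 0.0504). In shMyc cells the list's median was 0.25 and its mean -0.04, opposite in sign. Fry tests whether a list moves one way on balance and does not compare it with other regions.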

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

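Of the tests in this part, the one on the choice of scaling was chosen only after the result was seen. Each result here was singled out because the Paf1 response differed between shControl and shMyc cells by a test of the difference itself.

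The interaction passed at 39 eRNAs and 30 PROMPTs, and its median was 0.14 for eRNAs and -0.27 for PROMPTs. With library totals as scale the median was -0.20 for eRNAs and -0.60 for PROMPTs, so the eRNA sign depends on the scaling. The Kras-MAPK list of eRNAs had an interaction fry adjusted p = 0.0433, and an adjusted p = 0.839 with an estimated correlation. It was lost with library totals (fry adjusted p = 0.558), TMM inside each table (fry adjusted p = 0.218) and a replicate block (fry adjusted p = 0.0504). Among named eRNAs the log2 interaction was 4.0 near Ifngr1, 3.41 near Ier5, 3.38 on chromosome 7 at 145045672, 2.98 near Cebpb, 2.91 on chromosome 5 at 64579137 and 2.88 near Ly6e. It was -2.82 near Clstn3, -2.66 near Kansl1, -1.78 near Lgalsl, -1.61 near Ppcdc, -1.54 near Krt78 and -0.98 on chromosome 6 at 43442405, antisense to Tpk1. Among PROMPTs it was 2.01 at Tmco4, 1.85 at Ccdc43, 1.83 at Ezh2, 1.62 at Card10, 1.54 at Aqp5 and 1.40 at Rps6ka4. It was -1.90 at Per2, -1.76 at Txn1, -1.75 at Lrrfip2, -1.55 at Klf9, -1.23 at Smg9 and -1.19 at Irf2bp2. Of the 4 scalings, chromosome 7, Ccdc43, Txn1, Lrrfip2 and Smg9 were called under 2, and Kansl1, chromosome 6, Ezh2, Card10 and Rps6ka4 under 3.

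The call at chromosome 7 was lost without double knockdown library 1, Myc knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.171) and that at Kansl1 was lost without Myc knockdown library 1, double knockdown library 1, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.441). The call at Lgalsl was lost without Myc knockdown library 1, double knockdown library 1, control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.131) and that at Ppcdc was lost without Myc knockdown library 1, double knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.175). The call at Krt78 was lost without control libraries 1 or 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.118) and that at chromosome 6 was lost without double knockdown library 1, Myc knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.193). The call at Ccdc43 was lost without Myc knockdown library 1, double knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.244) and that at Ezh2 was lost without Myc knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.160). The call at Card10 was lost without double knockdown library 1, Myc knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.366) and that at Rps6ka4 was lost without Myc knockdown libraries 1 or 2, double knockdown library 1, control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.177). The call at Per2 was lost without control library 1 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.122) and that at Txn1 was lost without Myc knockdown library 1, double knockdown library 1, control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.270). The call at Lrrfip2 was lost without Myc knockdown libraries 1 or 2, double knockdown library 2, control libraries 1 or 2 or Paf1 knockdown libraries 1 or 2 (edgeR adjusted p up to 0.156) and that at Klf9 was lost without double knockdown library 2, control library 1 or Paf1 knockdown library 2 (edgeR adjusted p up to 0.107). The call at Smg9 was lost without Myc knockdown library 1, double knockdown library 2, control libraries 1 or 2 or Paf1 knockdown library 1 (edgeR adjusted p up to 0.225). With 1 library left out, the log2 interaction ran from 2.92 to 8.46 at Ifngr1, from -3.38 to -1.42 at Kansl1 and from -2.50 to -0.98 at Krt78. Among PROMPTs the log2 interaction then ran from 1.29 to 2.88 at Ezh2 and from 0.99 to 2.03 at Card10. Among eRNAs, calls were lost with the DESeq2 Wald test at Kansl1, Lgalsl, Ppcdc, Krt78 and chromosome 6, with no filter on low counts at Kansl1, Lgalsl, Ppcdc and chromosome 6 and with a replicate block at chromosome 7, Kansl1, Lgalsl, Ppcdc, Krt78 and chromosome 6. DESeq2 gave no adjusted value at chromosome 7, Ly6e and Clstn3, set aside by its own filter. Among PROMPTs, calls were lost with the DESeq2 Wald test at Rps6ka4, Per2, Klf9 and Smg9, with no filter on low counts at Txn1, Lrrfip2 and Smg9 and with the stricter filter at Ccdc43. They were also lost without PROMPTs over another gene at Ccdc43 and Lrrfip2 and with a replicate block at Ccdc43, Ezh2, Card10, Rps6ka4, Txn1, Lrrfip2 and Smg9. DESeq2 gave no adjusted value at Ccdc43, Ezh2, Card10, Txn1 and Lrrfip2, set aside by its own filter.

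The eRNAs that fell after Paf1 knockdown in shControl cells responded less in shMyc cells. Selection on noise of single libraries is argued against: of 38 regions chosen from the replicate 1 libraries alone, 38 were lower in the replicate 2 libraries. Their median log2 change there was -1.66, against -0.19 in shMyc cells, a difference of -1.47 (95% bootstrap interval over regions -1.86 to -1.13). That interval covers regions and not libraries. The libraries of a group may be technical, so a deviation they share is not excluded, and no minimum count was asked in Myc knockdown. At least 20 of the 53 lower regions had a positive interaction past the threshold under each of the 4 scalings. Their fall enters the interaction with the opposite sign, so the way they were chosen favours this, and it does not settle the choice of scaling. Over all eRNAs the interaction was positive at 31 and negative at 8 in the main fit, and at 21 and 21 with library totals. Too few counts in shMyc cells stays open, because 24 of the 53 regions held under 20 normalised counts in Myc knockdown. The other 29 had a median log2 change of -1.19 in shControl and -0.0503 in shMyc cells, a ratio of 0.0422 (interval -0.105 to 0.298), and 17 of them had a positive interaction. A difference of the control libraries alone stays open too. A high level in control alone would give a fall, no response in shMyc cells and a positive interaction together. Of the 53 regions, 40 were also lower after Myc knockdown against the same control libraries. Of the 48 eRNAs called the same way after Paf1 and Myc knockdown, 15 differed between Paf1 and Myc knockdown, and the rest do not decide it. Whether the Paf1 response depends on Myc itself may be asked only as a hypothesis. It is untested apart from doxycycline, which went with each Paf1 knockdown, and from other differences between shMyc and shControl cells.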

How the results depend on the processing

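TMM inside each table and the crossed replicate block were chosen only after the data were seen. Of 110 named results (81 regions), 0 reversed, 55 lost their call under at least 1 setting and 52 with a library left out. Named regions were chosen for large changes past the threshold, so a reversal was unlikely from the start. For the changes below the cause was not tested, except that fewer regions or libraries enter some settings. The DESeq2 Wald test gave an adjusted value for 90 of the named results. A pseudocount does not apply to counts, and the DESeq2 Wald test and the crossed block give no median. TMM inside each table centres each class on itself, so class medians were not tested under it. The depth of these tables limits single regions: 2-fold changes were recovered for 46.5% of simulated regions.

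With library totals as scale, the eRNA median changed sign, to 0.148 for Paf1 in shControl cells, 0.00613 for Paf1 in shMyc cells, 0.127 for Myc without Paf1 knockdown, -0.20 for the interaction. With library totals as scale, PROMPT calls numbered 84 (against 48) for Paf1 in shControl cells, 56 (against 30) for the interaction. With library totals as scale, the PROMPT median changed sign, to 0.00678 for Paf1 in shMyc cells. With the DESeq2 Wald test, eRNA calls numbered 38 (against 71) for Paf1 in shControl cells, 67 (against 112) for Myc without Paf1 knockdown, 33 (against 63) for Myc with Paf1 knockdown, 20 (against 39) for the interaction. With the DESeq2 Wald test, PROMPT calls numbered 25 (against 48) for Paf1 in shControl cells, 10 (against 36) for Paf1 in shMyc cells, 38 (against 72) for Myc without Paf1 knockdown, 17 (against 40) for Myc with Paf1 knockdown, 10 (against 30) for the interaction. Without eRNAs over gene bodies and PROMPTs over another gene, eRNA calls numbered 35 (against 71) for Paf1 in shControl cells, 0 (against 2) for Paf1 in shMyc cells, 68 (against 112) for Myc without Paf1 knockdown, 29 (against 63) for Myc with Paf1 knockdown, 21 (against 39) for the interaction. Without eRNAs over gene bodies and PROMPTs over another gene, the eRNA median changed sign, to 0.0422 for Paf1 in shMyc cells. The eRNA median no longer passed without eRNAs over gene bodies and PROMPTs over another gene, at -0.0571 for Myc with Paf1 knockdown. Without eRNAs over gene bodies and PROMPTs over another gene, the PROMPT median passed, at 0.0975 for Myc with Paf1 knockdown. With no filter on low counts, eRNA calls numbered 1 (against 2) for Paf1 in shMyc cells. With no filter on low counts, the eRNA median changed sign, to 0.00136 for Myc with Paf1 knockdown. The PROMPT median no longer passed with no filter on low counts, at -0.283 for the interaction. With DESeq2 size factors, eRNA calls numbered 0 (against 2) for Paf1 in shMyc cells. With DESeq2 size factors, the eRNA median changed sign, to 0.0193 for Paf1 in shMyc cells. The eRNA median no longer passed with DESeq2 size factors, at -0.0340 for Myc with Paf1 knockdown. With DESeq2 size factors, the PROMPT median changed sign, to 0.0184 for Paf1 in shMyc cells. With DESeq2 size factors, the PROMPT median passed, at 0.0838 for Myc with Paf1 knockdown. With only the 4 libraries compared, eRNA calls numbered 0 (against 2) for Paf1 in shMyc cells. With TMM inside each table, eRNA calls numbered 0 (against 2) for Paf1 in shMyc cells.

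The replicate number does not pair the libraries: deviations of same-numbered libraries correlated between -0.13 and 0.13. With a replicate block, eRNA calls numbered 0 for Paf1 in shMyc cells, and PROMPT calls 21 for Paf1 in shMyc cells, 26 for Myc with Paf1 knockdown and 12 for the interaction; the other counts stayed within 1.5 times. With a crossed replicate block, fitted to the 4 libraries compared alone, eRNA calls for Myc with Paf1 knockdown numbered 10. That fit also had fewer residual degrees of freedom than the main fit.

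Leaving out each library in turn, eRNA calls ranged over 37 to 74 for Paf1 in shControl cells, 0 to 9 for Paf1 in shMyc cells, 83 to 114 for Myc without Paf1 knockdown, 39 to 67 for Myc with Paf1 knockdown, 21 to 41 for the interaction. In the same fits, eRNA medians ranged over -0.250 to -0.198 for Paf1 in shControl cells, -0.0508 to 0.0463 for Paf1 in shMyc cells, -0.274 to -0.153 for Myc without Paf1 knockdown, -0.101 to -0.0790 for Myc with Paf1 knockdown, 0.0792 to 0.288 for the interaction. Leaving out each library in turn, PROMPT calls ranged over 24 to 49 for Paf1 in shControl cells, 11 to 42 for Paf1 in shMyc cells, 42 to 74 for Myc without Paf1 knockdown, 22 to 41 for Myc with Paf1 knockdown, 5 to 34 for the interaction. In the same fits, PROMPT medians ranged over 0.226 to 0.269 for Paf1 in shControl cells, -0.0534 to 0.0257 for Paf1 in shMyc cells, 0.181 to 0.323 for Myc without Paf1 knockdown, 0.0351 to 0.105 for Myc with Paf1 knockdown, -0.330 to -0.197 for the interaction.

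For the Kras-MAPK list, the adjusted p for Paf1 in shControl cells was 0.241 with library totals, 0.0673 with TMM inside each table, 0.776 in camera with a preset and 0.782 with an estimated correlation. For Myc with Paf1 knockdown it was 0.201 and 0.254 in camera. For the interaction it was 0.558 with library totals, 0.218 with TMM inside each table, 0.0504 with a replicate block, and 0.834 and 0.839 in camera. In the more abundant regions of each table, the correlation of Myc responses was 0.668 for eRNAs and 0.520 for PROMPTs, and that of Paf1 responses 0.269 for PROMPTs.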

Other observations

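The tests of counts per library, of doxycycline as the whole cause and of shared-control noise with its split of the controls, and the split by length with its replicate and interaction checks, were chosen only after the results were seen.

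Long and short PROMPTs differed in their Paf1 response in shMyc cells. Of the 76 longest (3801 to 18802 bp), 17 were higher and 3 lower, with a median log2 change of 0.26. The 77 shortest (517 to 2201 bp) had a median of -0.27. In shControl cells the medians were 0.31 and 0.21.

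Length was set against the signed log2 change after Paf1 knockdown, which bears on direction and not on the size of the change. This gave 4 of 6 correlations in the family, all across regions or pairs, which are not independent replicates. For PROMPTs in shMyc cells the Spearman correlation of length and log2 change was 0.340 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give; Benjamini-Hochberg adjusted p = 6.0e-05). It was 0.399 with mean level held fixed, and 0.269 and 0.303 in the libraries numbered 1 and 2. In shControl cells it was 0.0368 for PROMPTs (permutation p = 0.581, adjusted p = 0.895). For eRNAs it was -0.0326 in shControl cells (permutation p = 0.597, adjusted p = 0.895) and 0.116 in shMyc cells (permutation p = 0.0578, adjusted p = 0.173). With mean level held fixed, it was 0.0406 and 0.212 for eRNAs in shControl and shMyc cells, and 0.0916 for PROMPTs in shControl cells. No test was run on the values with level held fixed. Length also correlated with the PROMPT interaction (0.188, permutation p = 0.0048). That length may go with the direction of the PROMPT response when Myc is depleted is a hypothesis.

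The eRNA share was lower in the 3 knockdown groups than in control. A few abundant regions are argued against as the whole cause: without the 20 most abundant regions of each table, which held 45.9% of the counts, control still exceeded Paf1 knockdown by 7.17 percentage points, against 10.1 with them. It exceeded Myc knockdown by 6.57 points, against 12.8 with them, so those regions carry a large part of the Myc shift. The 12.8 points argue against the number of counts per library, since their totals overlap, and against doxycycline as the whole cause, since the labels name none for Myc knockdown. Doxycycline as the cause of the Paf1 part cannot be told apart from Paf1 knockdown. An effect of Paf1 or Myc depletion on eRNAs or on PROMPTs may underlie the shift and was not tested.

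eRNA changes after Paf1 and after Myc knockdown went the same way. Noise of the shared controls is argued against as the whole cause. With a separate control library for each contrast, the covariance of changes in log2 normalised counts was 0.648 and 0.669. With the same library for both it was 0.776 and 0.842. The covariance of the fitted log2 changes, 0.801, also lay above the highest of 50 simulated values, 0.20. Those simulations gave all regions of a class a common spread, estimated between libraries that may be technical, so they may understate this noise. Differences of whole chromosomes are argued against as the main cause, since 89.1% of the covariance was left after centring each chromosome on its median. The spread of chromosome medians of the Myc change had a permutation p = 0.157. This centring does not remove copy number changes of part of a chromosome, which stay open. A difference of the control libraries alone stays open: 15 of the 48 regions called the same way in both contrasts (31.2%) differed between Myc and Paf1 knockdown, and the rest do not decide it. Enhancers that need both Paf1 and Myc are the biological alternative, untested here.

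Whether eRNAs of opposite strand within 5 kb move together could not be decided, because no more than 3 pairs of separate regions were left. Their Spearman correlation was 0.50 after Myc knockdown and 0.50 after Paf1 knockdown in shControl cells (permutation p = 1 for both). With 3 pairs, 0.50 is the smallest size this correlation can take, so that p was fixed in advance.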
